A study of Mus musculus with 8 samples.

How the data were processed

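RNA was measured in CD11b bead-purified microglia of the mouse lateral geniculate nucleus, without injury (2 libraries) and 1 day (3 libraries) or 3 days (3 libraries) after crush of both optic nerves. Per the labels' protocols, RNA was extracted with a column kit for small samples and linearly amplified before libraries were made. The deposited values are raw read counts per Ensembl gene, 1 column per library. The submitters' processing notes name FastQC, STAR and HTSeq and the mouse build mm9. Their versions, the gene annotation and the strand setting are not given in the sources used here. Groups were taken from the sample labels, and columns were matched to samples by name. All 8 sample descriptions carry the same flow cell code, so no batch could be separated.

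The table held 26062 gene IDs, of which 25925 matched a symbol in GENCODE M21, and the rest took 0.127% of the counts. Exon overlaps and lengths also came from GENCODE M21, whose build differs from mm9, so no coordinates are given. Of 234 named genes found in that annotation, 64 share exonic bases with another gene, 10 of them on the same strand. No 2 libraries of a group had counts within sampling noise of each other (chi-square per degree of freedom 31.4 to 64.8), so each library counted as 1 replicate.

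Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 3 groups with its defaults, which left 17390 genes, TMM scaling, a robust quasi-likelihood fit of all 8 libraries with 1 mean per group, and F-tests for each pair of groups. All 8 libraries shared 1 estimate of the spread because the uninjured group has 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. An adjusted p over the members of a list alone is given where named. The biological coefficient of variation was 51.1%. Levels are TMM-scaled CPM, and the standard error of a log2 fold change is its size divided by the square root of F. Where a group had no count, the fold is a lower bound against 3 counts summed over the group. With 1 to 3 counts, the ratio of counts is given with an exact binomial 95% interval, which covers counting error alone.

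Gene lists were tested with camera (limma 3.58.1) at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list passed at an adjusted p under 0.05. The 27 lists, 16 of microglial biology and 11 of cell type markers, were fixed before the data were examined, as were the tests and the rule for named genes. Lists share members, such as Itgam (complement, purinergic and chemotactic sensing) and Lpl (disease-associated, lipid). The rule takes, for each comparison, the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between libraries, the up to 4 members of each list with the smallest p, and 12 fixed genes (C1qa, C1qb, C1qc, C3, P2ry12, Tmem119, Cx3cr1, Trem2, Apoe, Cd68, Mertk and Itgam). It leaves out symbols of predicted genes, unnamed clones and small RNAs, and olfactory, immunoglobulin and T cell receptor segments.

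The procedure was tested on simulated counts with the spread and library sizes of the data, 5 times per comparison, with 100 genes changed 2-fold and 100 changed 4-fold in each. It recovered 14.2%, 11.6% and 19.4% of the 2-fold changes and 44.8%, 47.4% and 52.6% of the 4-fold changes at 1 day, at 3 days and between the times, and 7.23%, 5.45% and 6.01% of the calls were false. The lists of the study, whose members were changed only where picked at random, were tested 133, 134 and 133 times, and camera called 1, 0 and 0. A list of 30 genes raised 2-fold was called in 5 of 5 simulations of each comparison. Genes were drawn independently of each other, so these rates say nothing of lists whose members vary together.

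The alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, other scaling and filters, a fit to the libraries of 2 groups, the replicate number as a block, a test against a 1.5-fold change, an estimated correlation between genes, fry, and each library left out in turn. A covariate for choroid plexus markers, leaving out mitochondrially encoded genes and thinning to equal depth were added after seeing the data.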

Results

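Gene expression was measured by RNA sequencing in microglia, the resident macrophages of the brain, taken from the lateral geniculate nucleus (LGN), the thalamic relay that receives retinal axons. The cells came from adult male C57BL/6J mice aged 2 to 3 months and were purified on magnetic beads against CD11b, the integrin subunit encoded by Itgam. Uninjured mice gave 2 libraries, mice killed 1 day after crush of both optic nerves gave 3, and mice killed 3 days after crush gave 3. Optic nerve crush breaks the axons of retinal ganglion cells, whose terminals lie in the LGN. Library totals were 17533499 and 17994861 counts for uninjured mice, 12700098, 13762009 and 15489477 at 1 day, and 14993580, 13769396 and 13756487 at 3 days. The number of genes with a count was 22029 ± 518 (mean ± SD, n = 2), 18969 ± 1127 (n = 3) and 20807 ± 213 (n = 3), so fewer genes were detected at 1 day. Mitochondrially encoded genes took 21.9 ± 0.849%, 16.5 ± 4.70% and 27.3 ± 3.99% of the counts. Correlations of log2 CPM between libraries of a group were 0.939 for the uninjured pair, 0.888 to 0.908 at 1 day and 0.925 to 0.931 at 3 days. Day 1 replicate 3 had a correlation of 0.926 with control replicate 2, above those within its own group. The 1 day libraries lay at 120.4, 63.8 and 52.3 on the first principal component (32.6% of the variance) and at 7.54, −93.4 and 36.3 on the second (17.6%), and replicates 1 to 3 had 13.6%, 21.9% and 13.9% mitochondrially encoded counts. Xist stayed at or under 1.84 CPM (counts scaled to a common library size) and Ddx3y at or above 66.0 CPM in all 8 libraries, as in male tissue. The labels do not say whether a library came from a single animal or a pool, so p-values measure only the spread between these libraries, which may be technical.

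The first comparison asked how LGN microglia differed from those of uninjured mice 1 day after axon injury. Il1b (ENSMUSG00000027398), which encodes the cytokine interleukin-1 beta, rose from 119.5 ± 3.26 CPM in uninjured mice (SD, n = 2) to 412 ± 117 CPM at 1 day (SD, n = 3), a log2 fold change of 1.79 (SE 0.22, adjusted p = 0.00132). Il1a, its alpha counterpart, rose from 718 ± 109 to 2041 ± 342 CPM (log2 fold change 1.51, SE 0.18, adjusted p = 0.00132), and Nlrp3, the sensor of an inflammasome that processes interleukin-1 beta, rose from 169 ± 2.06 to 524 ± 29.8 CPM (1.63, SE 0.17, adjusted p = 0.00113). In the same libraries endothelial markers were lower: 10 of 15 fell, and the list had a median log2 fold change of −1.13.

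Of 33 inflammatory cytokine and NF-kB target genes tested, 14 rose and 0 fell, and 24 rose when adjusted over the list alone. Their median log2 fold change was 0.89, and the list passed the camera test (adjusted p = 9.83e-32, adjusted p = 0.0658 with an estimated correlation). Among the risers was Tnfaip2, a TNF-induced gene, at 1.49 (SE 0.19, adjusted p = 0.00192). The number of risers was 4 without control replicate 1, 9 without control replicate 2 and 9 without day 3 replicate 3. The day 3 libraries enter through the shared estimate of spread. Il1b, Il1a, Nlrp3 and Tnfaip2 rose with each of the 8 libraries left out in turn. Other large rises were Gpr84, a receptor for medium-chain fatty acids (435 ± 59.7 to 1586 ± 482 CPM, adjusted p = 0.00175), and Mthfsl (87.2 ± 4.58 to 263 ± 58.6 CPM, adjusted p = 0.00269).

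Immediate early and heat shock genes, which respond within minutes to stimulation and to tissue dissociation, had 5 risers of 29 (14 adjusted over the list alone) and a median log2 fold change of 0.57. The list passed (adjusted p = 2.95e-10, adjusted p = 0.126 with an estimated correlation). Egr1, an immediate early transcription factor, rose from 2585 ± 465 to 5283 ± 410 CPM (adjusted p = 0.00324) and had an adjusted p of 0.0516 without control replicate 1. The number of risers in the list was 0 without control replicate 1 (edgeR, where the list itself still passed), 2 without day 1 replicate 1, day 1 replicate 2 or day 3 replicate 3, and 3 without day 3 replicate 1. Of 23 purinergic and chemotactic sensing genes, 3 rose and 0 fell (4 rose and 1 fell adjusted over the list alone, median 0.31, adjusted p = 0.000235, adjusted p = 0.126 with an estimated correlation), with 1 riser without control replicate 1. The 3 were Itgam, the complement receptor C5ar1 and the nucleotide receptor P2ry6. Itgam rose from 508 ± 125 to 1282 ± 130 CPM (log2 fold change 1.34, SE 0.17, adjusted p = 0.00173), also with each library left out in turn. In the annotation used here 3450 of the 5024 exonic bases of Itgam are shared with Gm49368, a gene counted separately in the table, so its level may rest on part of its transcript.

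Complement genes passed as a list (median log2 fold change 0.47, adjusted p = 0.00162, adjusted p = 0.126 with an estimated correlation) with 2 risers, Itgam and C5ar1, and 1 gene that fell, Cd59a, of 20 tested (8 and 1 adjusted over the list alone). Leaving out control replicate 1 gave 1 riser and 0 that fell, control replicate 2 gave 4 risers, and Cd59a was not called without day 1 replicate 2, day 1 replicate 3, day 3 replicate 1 or day 3 replicate 3. C1qa, C1qb, C1qc and C3 were not called, and C1qb had 1094 ± 464 CPM in uninjured mice and 1667 ± 258 CPM at 1 day (adjusted p = 0.187). A further 5 lists of microglial biology passed with no member called by edgeR over all genes. Homeostatic microglia genes were higher in 20 of 22 cases (median 0.40, adjusted p = 2.74e-06, adjusted p = 0.304 with an estimated correlation), with 12 members at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2. Lysosome genes were higher in 37 of 40 cases (median 0.30, adjusted p = 1.45e-06, adjusted p = 0.126 with an estimated correlation), with 17 at an unadjusted p under 0.05, 3 adjusted over the list alone and 2 by DESeq2.

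MHC and antigen presentation genes had a median of 0.46 (adjusted p = 0.00129, adjusted p = 0.304 with an estimated correlation, 8 of 27 at an unadjusted p under 0.05, 6 adjusted over the list alone, 2 by DESeq2). Disease-associated microglia genes had a median of 0.33 (adjusted p = 0.00919, adjusted p = 0.34 with an estimated correlation, 9 of 25 at an unadjusted p under 0.05, 4 adjusted over the list alone, 2 by DESeq2) and an adjusted p of 0.466 without day 1 replicate 2. Engulfment receptor and signalling genes had a median of 0.19 (adjusted p = 0.029, adjusted p = 0.34 with an estimated correlation). Of 36 members, 11 were higher and 2 lower at an unadjusted p under 0.05, 1 rose and 1 fell adjusted over the list alone, and DESeq2 called 1 as rising and 2 as falling. That list did not pass without control replicate 1, day 1 replicate 2, day 3 replicate 2 or day 3 replicate 3 (highest adjusted p = 0.352). Each of these 5 lists gained 1 riser without control replicate 2, the lysosome list 1 without day 1 replicate 3, the disease-associated list 1 without day 1 replicate 1 or day 1 replicate 3, and 1 engulfment gene fell without day 1 replicate 2.

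Among 37 mitosis genes, 2 rose and 1 fell (2 and 4 adjusted over the list alone), with a median of −0.18 and a test in the falling direction (adjusted p = 0.00845, adjusted p = 0.34 with an estimated correlation, 0.273 without day 1 replicate 1). Nusap1, a spindle protein gene, fell from 3.89 ± 0.471 to 0.503 ± 0.171 CPM (log2 fold change −2.93, SE 0.40, adjusted p = 0.00269). Ckap2l went the other way, from 19.4 ± 0.649 to 96.2 ± 22.0 CPM (2.31, SE 0.26, adjusted p = 0.00113). In the annotation it lies directly downstream of Il1a on the same strand. The other riser was Melk, absent from the uninjured pair and at 0.844 ± 0.290 CPM at 1 day, at least 10.7-fold higher. The riser count was 1 without control replicate 1, control replicate 2, day 3 replicate 2 or day 3 replicate 3, and 2, 3 and 4 genes fell without day 1 replicates 1, 2 and 3. DNA replication (adjusted p = 0.151), glycolysis (0.341) and oxidative phosphorylation genes (0.484) did not pass at 1 day.

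Of the 11 marker lists, 5 passed as lower at 1 day: endothelial, mural, choroid plexus and ependyma, astrocyte and erythroid. Neuron (median 0.50, adjusted p = 0.914), monocyte (0.47, adjusted p = 0.908), neutrophil (0.48, adjusted p = 0.0846) and border macrophage markers (0.01, adjusted p = 0.957) did not pass. The 10 endothelial markers that fell (11 of 15 adjusted over the list alone) were led by Slco1c1, a blood-brain barrier transporter, from 128 ± 41.0 to 36.3 ± 3.77 CPM (log2 fold change −1.82, SE 0.22, adjusted p = 0.00132). The list passed with both correlations (adjusted p = 2.91e-21, adjusted p = 0.0341 with an estimated correlation). Of these markers 2 fell without control replicate 1 and 5 without control replicate 2. Of 11 mural cell markers 1 fell, the pericyte gene Rgs5 (1000 ± 117 to 462 ± 57.4 CPM), and 3 fell adjusted over the list alone (list adjusted p = 0.00105, adjusted p = 0.117 with an estimated correlation). Mural markers numbered 2 that fell without day 1 replicate 2 or day 1 replicate 3. Choroid plexus and ependyma markers had 2 of 8 members called as falling, Folr1 and Kcne2, 8 adjusted over the list alone and 6 by DESeq2, with a median of −7.32 as fitted and −6.92 with absent genes at their bound (adjusted p = 1.95e-13, adjusted p = 0.126 with an estimated correlation). Neither was called without control replicate 1, day 1 replicate 1, day 1 replicate 2 or day 1 replicate 3. Only 1 was called without day 3 replicate 3 and 4 without day 3 replicate 2. Ttr, the choroid plexus gene for transthyretin, stood at 5157 and 484 CPM in the uninjured pair, at 0.467, 54.2 and 0.986 CPM at 1 day, and at 3309, 591 and 1815 CPM at 3 days. Astrocyte markers (median −0.49, adjusted p = 0.0111, adjusted p = 0.34 with an estimated correlation, 1 of 12 fell, the connexin gene Gjb6, and 2 adjusted over the list alone) and erythroid markers (median −1.93, adjusted p = 0.0182, adjusted p = 0.141 with an estimated correlation, 0 of 3 fell by edgeR, 2 at an unadjusted p under 0.05, 1 adjusted over the list alone, 0 by DESeq2) passed in the same direction. Without control replicate 1 or day 1 replicate 1 the astrocyte list did not pass (adjusted p = 0.285 and 0.0861), nor did the erythroid list without day 1 replicate 2 (0.053). Gjb6 was not called without control replicate 2, and 2 astrocyte markers fell without day 1 replicate 3.

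In all, 308 of 17390 genes were called at 1 day, 106 higher and 202 lower. The share that was higher, 34.4%, depended on the method: it was 53.3% with limma-voom, 57.7% with limma-voom and sample weights and 16.5% with scaling by library size alone. The 8 largest falls were Lrriq1, Frem1, Htr2c, Prr32, Sostdc1, Kcnk1, Dsg2 and Esrrg. Of these, 6 had no count in any 1 day library and were at least 85.0-fold (Esrrg) to 151-fold (Lrriq1) lower, against a floor of 3 counts over the group. Htr2c and Sostdc1 had 1 count, with ratios of 1419 (95% interval 254 to 56102) and 1338 (239.6 to 52875) that cover counting error only. In uninjured replicates these genes varied about as much as their mean, as for Lrriq1 at 10.9 ± 10.9 CPM. Lrriq1 fell with each library left out in turn, and 5 of the 8 were not called without control replicate 1. The genes called, day 1 vs control, numbered 39 without control replicate 1, 198 without day 1 replicate 1, 191 without day 3 replicate 1 and 155 without day 3 replicate 3. With the level of choroid plexus markers as a covariate, chosen after seeing the data, edgeR called 0 genes (933 at an unadjusted p under 0.05): the median rise went from 0.95 (median SE 0.19) to 0.89 (median SE 0.36) and the median fall from 2.51 (0.46) to 1.73 (0.90). The covariate separates the 1 day libraries from the rest, and what part smaller changes and larger errors had in the loss of calls was not tested.

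**Figure D1:**
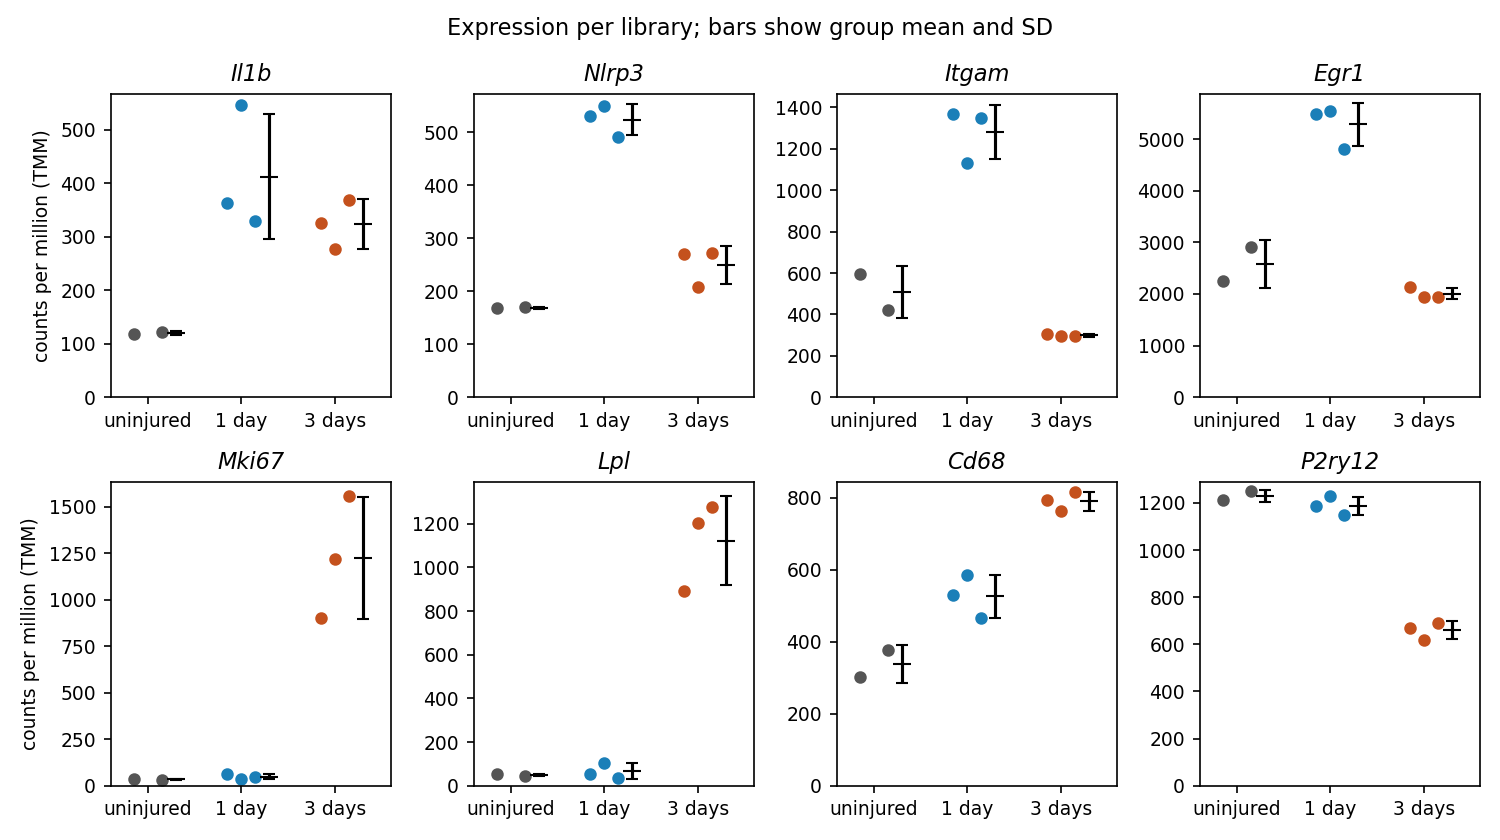
CPM (TMM-scaled, vertical axis from 0) of 8 genes in each library of uninjured mice (n = 2) and of mice 1 day (n = 3) and 3 days (n = 3) after crush, with points for libraries and bars for the group mean and SD. Il1b, Nlrp3, Itgam and Egr1 were highest at 1 day, Mki67, Lpl and Cd68 at 3 days, and P2ry12 was at 660 CPM at 3 days against 1230 CPM in uninjured mice.

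The second comparison asked how microglia differed from uninjured ones 3 days after crush. Genes of cell division were higher. Mki67 (ENSMUSG00000031004), the gene of the proliferation marker Ki-67, rose from 33.6 ± 2.83 CPM (SD, n = 2) to 1225 ± 328 CPM (SD, n = 3), a log2 fold change of 5.19 (SE 0.29, adjusted p = 3.87e-07), and Top2a, the DNA topoisomerase of dividing cells, rose from 5.90 ± 0.330 to 302 ± 73.8 CPM (5.68, SE 0.44, adjusted p = 1.77e-05). Lpl, which encodes lipoprotein lipase, rose from 48.4 ± 5.40 to 1123 ± 203 CPM (4.54, SE 0.42, adjusted p = 0.000166). P2ry12, a nucleotide receptor of resting microglia, fell from 1230 ± 26.9 to 660 ± 37.2 CPM (−0.90, SE 0.13, adjusted p = 0.00139).

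Of 37 mitosis genes 28 rose and 0 fell (34 adjusted over the list alone), with a median log2 fold change of 4.32 (adjusted p = 6.28e-80, adjusted p = 0.00424 with an estimated correlation). Of 36 DNA replication genes 18 rose and 0 fell (30 adjusted over the list alone), with a median of 2.90 (adjusted p = 4.37e-45, adjusted p = 0.00224 with an estimated correlation). Clspn, a replication checkpoint gene, rose from 0.391 ± 0.175 to 37.7 ± 4.77 CPM, and Mcm5, a subunit of the replicative helicase, from 2.59 ± 0.193 to 54.0 ± 7.29 CPM. Melk and BC030867 had no count in the uninjured pair and were at least 118-fold and 109-fold higher. Mitosis risers numbered 15 without control replicate 1 and 18 without control replicate 2. Replication risers numbered 8, 9 and 11 without control replicate 1, control replicate 2 and day 3 replicate 3. Mki67, Top2a, Clspn, Mcm5, Melk and BC030867 rose with each library left out in turn. In the same libraries monocyte (median −0.57, list adjusted p = 0.158), neutrophil (−0.37, 0.158), lymphocyte and NK cell (−0.06, 0.343), mural (−0.29, 0.439), astrocyte (−0.996, 0.0607) and oligodendrocyte and precursor markers (−0.65, 0.178) did not pass. Lower astrocyte markers passed without control replicate 2 (adjusted p = 0.00505), day 1 replicate 2 (0.0379) or day 1 replicate 3 (0.0223), and lower oligodendrocyte markers without control replicate 1 (0.0256). Endothelial markers were lower as a list (median −0.37, adjusted p = 0.00538, adjusted p = 0.195 with an estimated correlation), with 0 of 15 called by edgeR, 5 lower at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2. Without day 1 replicate 2, edgeR called 1 of them as falling.

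Disease-associated microglia genes, a set described in neurodegeneration models, had 11 risers of 25 (17 adjusted over the list alone) and a median of 1.09 (adjusted p = 5.91e-22, adjusted p = 0.0482 with an estimated correlation). Without control replicate 1, 6 rose. Besides Lpl they included Spp1, the gene of osteopontin (27.8 ± 2.83 to 212 ± 62.4 CPM, adjusted p = 0.000646), the pyrophosphate transporter gene Ank (1.90, SE 0.26, adjusted p = 0.00084) and the protease gene Ctsb (1279 ± 220 to 3418 ± 186 CPM, adjusted p = 0.000273). Trem2 and Apoe were not called, at 0.65 (SE 0.22, adjusted p = 0.136) and 0.05 (SE 0.18, adjusted p = 0.941). Lysosome genes had 10 risers and 1 gene that fell, the cathepsin gene Ctss, of 40 (16 and 1 adjusted over the list alone, median 0.26, adjusted p = 3.95e-06, adjusted p = 0.144 with an estimated correlation). Cd68, a lysosomal membrane glycoprotein of phagocytes, rose from 339 ± 53.0 to 791 ± 26.8 CPM (1.22, SE 0.16, adjusted p = 0.000676), and Gusb, a lysosomal glucuronidase, from 151 ± 4.29 to 359 ± 16.9 CPM (adjusted p = 0.000415). Lysosome risers numbered 3 without control replicate 1, 5 without day 3 replicate 1 and 6 without control replicate 2, day 3 replicate 2 or day 3 replicate 3, and Ctss was not called without control replicate 1, control replicate 2, day 3 replicate 1 or day 3 replicate 3. Cd68, Gusb, Ctsb, Ank, Spp1 and Lpl rose with each library left out in turn.

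Inflammatory cytokine and NF-kB target genes had 8 risers of 33 and 0 that fell (13 and 2 adjusted over the list alone), with a median of 0.53 (adjusted p = 1.2e-10, adjusted p = 0.144 with an estimated correlation). Of the list, 2 fell without day 1 replicate 2 and 1 without day 3 replicate 2. Il12b, a subunit of interleukins 12 and 23, rose from 3.00 ± 0.596 to 69.1 ± 26.0 CPM (4.52, SE 0.46, adjusted p = 9.39e-05), the chemokine gene Ccl5 from 20.9 ± 1.69 to 108 ± 8.79 CPM (adjusted p = 0.000219) and the lipopolysaccharide co-receptor gene Cd14 from 225 ± 26.3 to 697 ± 83.7 CPM (adjusted p = 0.000954). Immediate early and heat shock genes had 8 members that fell of 29 and 0 that rose (14 fell adjusted over the list alone, median −0.43, adjusted p = 9.36e-09, adjusted p = 0.14 with an estimated correlation), led by the transcription factor Klf4 (341 ± 33.6 to 146 ± 20.8 CPM, adjusted p = 0.00264). Their number was 1 without control replicate 1, and 3 without control replicate 2, day 3 replicate 1 or day 3 replicate 3. Homeostatic microglia genes had 3 that fell of 22, P2ry12, Siglech and P2ry13 (6 fell and 1 rose adjusted over the list alone, median −0.34, adjusted p = 0.00698, adjusted p = 0.499 with an estimated correlation, 0.753 without control replicate 2). Their number was 1 without control replicate 2, day 3 replicate 1 or day 3 replicate 3. Cx3cr1, Tmem119 and Mertk were not called. Purinergic and chemotactic sensing genes did not pass as a list (adjusted p = 0.105), with 4 that fell and 1 that rose of 23. Lower expression of that list passed without control replicate 1 (0.0112) or day 3 replicate 3 (0.0498). Of its genes 2 fell without control replicate 1, control replicate 2, day 3 replicate 1 or day 3 replicate 3, and the riser, C5ar1, was not called without either control library or any 1 of the day 3 libraries. Border macrophage markers were lower (median −0.33, adjusted p = 0.0384, adjusted p = 0.15 with an estimated correlation, 1 of 14 fell, F13a1). Without control replicate 2 the border macrophage list had an adjusted p of 0.0806 and without day 3 replicate 3 of 0.0684. F13a1 was not called without either control library, day 3 replicate 1 or day 3 replicate 3, and 2 markers fell without day 1 replicate 2.

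Glycolysis genes had 5 risers of 20 and 0 that fell (7 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.000488, adjusted p = 0.0604 with an estimated correlation), among them Pkm, the gene of pyruvate kinase M (92.2 ± 3.30 to 340 ± 8.70 CPM, adjusted p = 0.000123), and Gapdh (90.4 ± 7.17 to 227 ± 44.2 CPM, adjusted p = 0.00162). Of these genes 2 rose without control replicate 1 and 3 without control replicate 2 or any 1 of the day 3 libraries, and 1 fell without day 1 replicate 2. Nuclear-encoded oxidative phosphorylation genes had 6 risers of 47 and 0 that fell (22 adjusted over the list alone), with 44 of 47 higher and a median of 0.87 (adjusted p = 4.14e-14, adjusted p = 0.108 with an estimated correlation). Cox6a1, a subunit of cytochrome c oxidase, rose from 21.7 ± 2.85 to 69.2 ± 8.30 CPM (1.67, SE 0.28, adjusted p = 0.00396, 0.0985 without control replicate 1). Those risers numbered 1 without either control library, 2 without day 3 replicate 1 or day 3 replicate 3, 3 without day 3 replicate 2, 12 without day 1 replicate 1 and 15 without day 1 replicate 2. Engulfment receptor and signalling genes (3 risers of 36, Fcer1g, Lrp1 and Rac1, median 0.01, adjusted p = 0.189), MHC and antigen presentation genes (adjusted p = 0.439), complement genes (0.769) and choroid plexus and ependyma markers (median −0.31, 0.96) did not pass. The engulfment list passed without control replicate 2 (adjusted p = 0.00652, 5 risers). It had 5 risers and 1 that fell without day 1 replicate 2, 1 riser without day 3 replicate 1 or day 3 replicate 2, and none called by edgeR without control replicate 1 or day 3 replicate 3. Choroid plexus markers passed as higher without control replicate 1 (adjusted p = 0.00527) and as lower without control replicate 2 (0.0167). C1qa, C1qb, C1qc and C3 were not called, with C1qb at 1529 ± 115 CPM (adjusted p = 0.281).

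In all, 604 of 17390 genes were called at 3 days, 433 higher and 171 lower. The 8 largest falls were Bnc2, Col12a1, Cpe, Otulinl, P3h2, Trappc6b, Sub1 and Ier5, with log2 fold changes of −1.54 to −2.67, and each of these calls was lost without control replicate 1. The genes called, day 3 vs control, numbered 108 without control replicate 1, 236 without control replicate 2, 276 without day 3 replicate 1, 172 without day 3 replicate 3 and 982 without day 1 replicate 2. Scaling by library size alone moved the median of all genes to −0.15 and the share of called genes that were higher from 71.7% to 56.5%. That share was 98.2% in a test against a 1.5-fold change. Of the called genes that changed over 2-fold, 363 were higher and 61 lower.

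**Figure D2:**
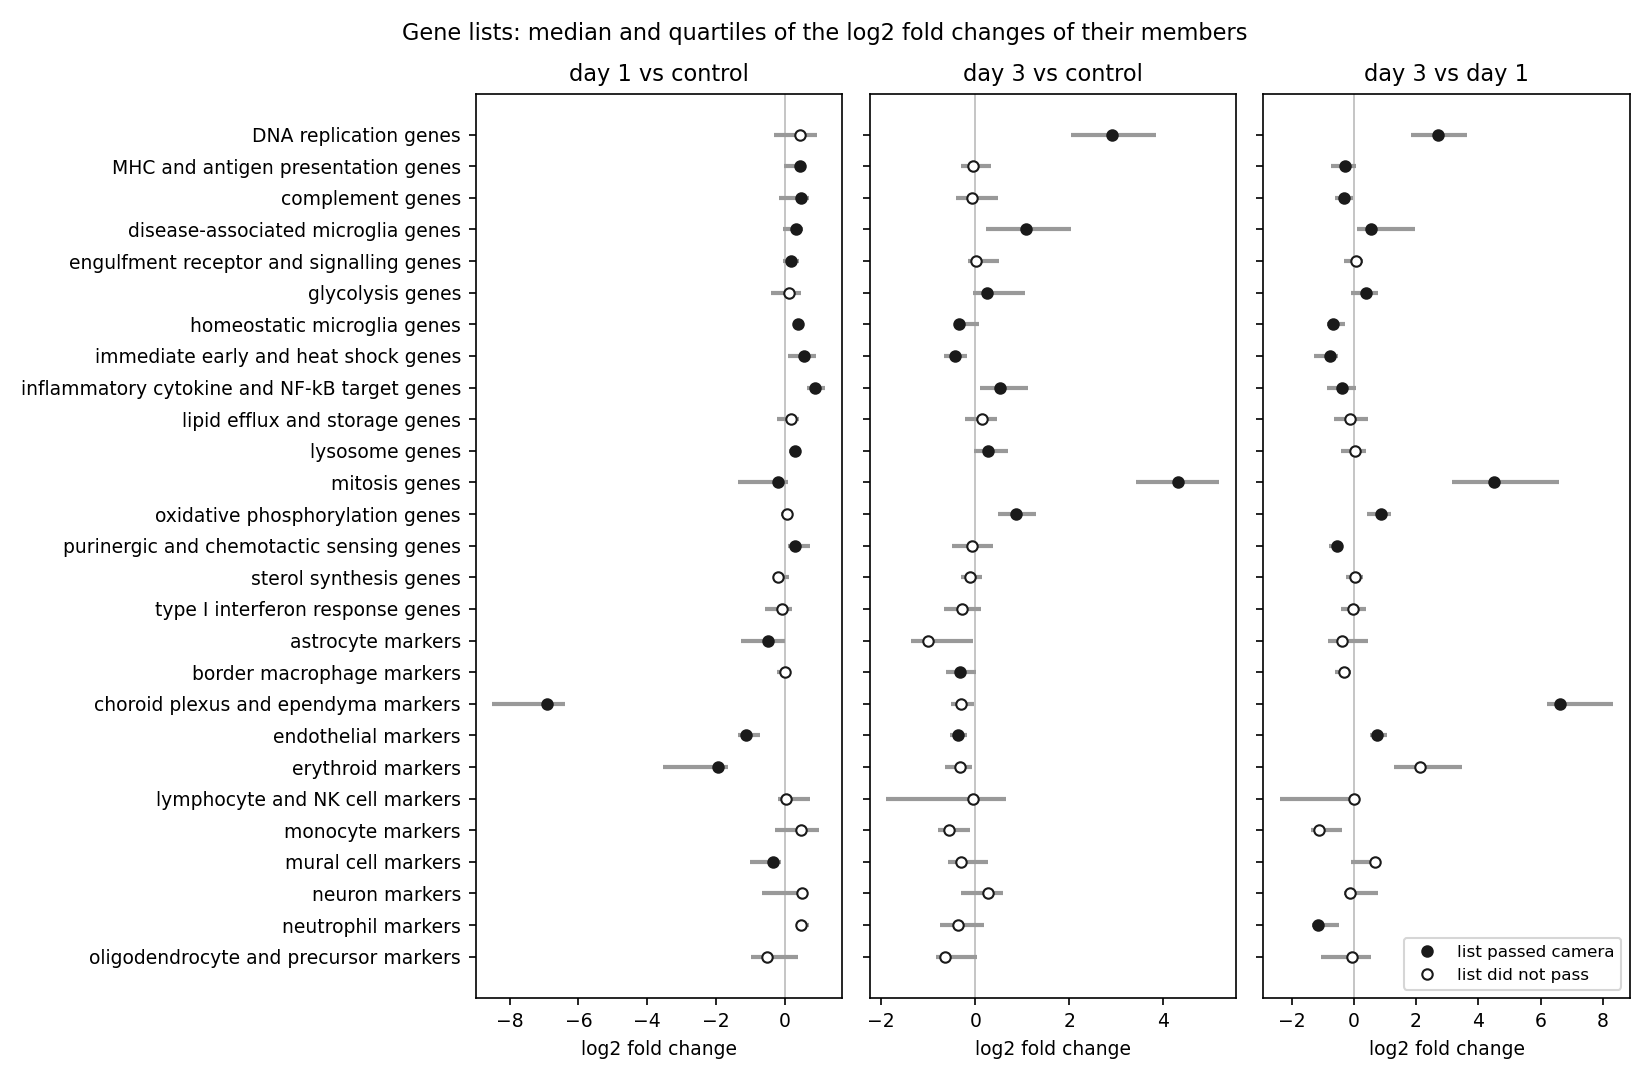
Median (points, with absent genes at their bound) and lower and upper quartiles (bars, fitted values) of the log2 fold changes of the tested members of 27 gene lists in each comparison. Each panel has its own horizontal scale, and filled points mark lists that passed camera with its preset correlation. Mitosis and DNA replication genes had medians of 4.32 and 2.90 at 3 days against uninjured mice, and inflammatory genes 0.89 at 1 day.

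The third comparison asked what differed between 1 and 3 days after crush. Mitosis and DNA replication genes were higher at 3 days than at 1 day, and immediate early and heat shock genes were lower. Nusap1 rose from 0.503 ± 0.171 to 72.6 ± 22.0 CPM (SD, n = 3 and 3, log2 fold change 7.15, SE 0.40, adjusted p = 2.15e-07) and Mki67 from 48.3 ± 12.05 to 1225 ± 328 CPM (4.66, SE 0.23, adjusted p = 9.68e-08). Itgam, whose product was the epitope of the bead selection, fell from 1282 ± 130 to 298 ± 5.07 CPM (−2.10, SE 0.15, adjusted p = 2.57e-06). Egr1 fell from 5283 ± 410 to 2005 ± 111 CPM (−1.40, SE 0.13, adjusted p = 2.77e-05).

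Mitosis genes had 32 risers of 37 (36 adjusted over the list alone, median 4.51, adjusted p = 5.51e-76, adjusted p = 0.00394 with an estimated correlation) and DNA replication genes 25 of 36 (29, median 2.70, adjusted p = 1.73e-31, adjusted p = 0.00394 with an estimated correlation). Spag5, Cdca5 and Cenph, all of the mitotic apparatus, had no count at 1 day and were at least 232-fold, 138-fold and 107-fold higher at 3 days. Disease-associated microglia genes had 11 risers of 25 (14, median 0.57, adjusted p = 1.85e-10, adjusted p = 0.0862 with an estimated correlation), led by Spp1 (20.0 ± 9.84 to 212 ± 62.4 CPM) and Lpl (65.6 ± 36.1 to 1123 ± 203 CPM). Oxidative phosphorylation genes had 20 risers of 47 (26, median 0.88, adjusted p = 1.17e-09, adjusted p = 0.134 with an estimated correlation), with Cox6a1 at 1.74 (SE 0.24, adjusted p = 0.00047). Of the list, 8 rose without day 1 replicate 1 or day 1 replicate 3, 6, 12 and 1 without day 3 replicates 1, 2 and 3. The second figures in these brackets are adjusted over the list alone. Glycolysis genes had 7 risers and 2 that fell of 20, and the same numbers adjusted over the list alone (median 0.38, adjusted p = 0.0231, adjusted p = 0.134 with an estimated correlation). The 2 that fell were Pfkfb3, which makes an activator of phosphofructokinase, and Hk2, a hexokinase named after its value was seen. That list had adjusted p up to 0.0769 and did not pass without day 1 replicate 3 or day 3 replicate 1. It had 4 risers without day 3 replicate 3, and 1 gene fell without day 1 replicate 2, day 1 replicate 3, day 3 replicate 2 or day 3 replicate 3.

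Immediate early and heat shock genes fell in 19 of 29 cases and rose in 0 (24 fell adjusted over the list alone), with all 29 lower and a median of −0.75 (adjusted p = 2.34e-25, adjusted p = 0.0316 with an estimated correlation). Homeostatic microglia genes fell in 12 of 22 cases (16 adjusted over the list alone, median −0.67, adjusted p = 1.29e-10, adjusted p = 0.157 with an estimated correlation), among them Siglech (769 ± 121 to 361 ± 23.03 CPM, adjusted p = 0.000573) and Tmem119 (746 ± 82.9 to 409 ± 10.4 CPM, adjusted p = 0.00394). Of 23 purinergic and chemotactic sensing genes 8 fell and 1 rose (11 and 1 adjusted over the list alone, median −0.54, adjusted p = 1.74e-06, adjusted p = 0.0862 with an estimated correlation), including Entpd1, the ectonucleotidase CD39 (adjusted p = 0.000318). Of these genes 4 fell without day 1 replicate 1 or day 3 replicate 3 and 5 without day 3 replicate 1 or day 3 replicate 2. The riser was S1pr1, named after its value was seen and not called without day 3 replicate 3.

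Inflammatory cytokine and NF-kB target genes had 10 that fell and 3 that rose of 33 (13 and 4 adjusted over the list alone, median −0.37, adjusted p = 0.000336, adjusted p = 0.278 with an estimated correlation, 0.0652 without day 1 replicate 2, where 5 rose). Il1a fell from 2041 ± 342 to 816 ± 102 CPM (adjusted p = 0.000135) and Nfkb1, an NF-kB subunit, from 871 ± 10.9 to 389 ± 9.89 CPM (adjusted p = 5.83e-05), while Il12b rose from 7.24 ± 2.95 to 69.1 ± 26.0 CPM (adjusted p = 9.42e-05). MHC and antigen presentation genes had 7 that fell of 27 (7 adjusted over the list alone, median −0.29, adjusted p = 0.000567, adjusted p = 0.184 with an estimated correlation, 4 without day 3 replicate 3, and 1 rose without day 1 replicate 2), with H2-K1 from 1113 ± 104 to 487 ± 58.8 CPM (adjusted p = 0.000106). Class I genes are near-identical copies, so how reads divide among them is uncertain. Complement genes had 4 that fell and 1 that rose of 20 (5 and 2 adjusted over the list alone, median −0.32, adjusted p = 0.0231, adjusted p = 0.184 with an estimated correlation). That list had an adjusted p of up to 0.115 and did not pass without day 1 replicate 2 or day 3 replicate 2, 2 genes fell without day 3 replicate 1 or day 3 replicate 3, 2 rose without day 1 replicate 2 and 0 rose by edgeR without day 3 replicate 3. Mertk, a receptor for apoptotic cells on the engulfment list, fell from 749 ± 65.9 to 381 ± 51.4 CPM (−0.97, SE 0.14, adjusted p = 0.000542), but that list had 2 risers and 4 that fell of 36 and did not pass (adjusted p = 0.696). On it 1 rose without day 1 replicate 2, day 1 replicate 3 or day 3 replicate 2, 0 by edgeR without day 1 replicate 1, day 3 replicate 1 or day 3 replicate 3, and 2 fell without day 3 replicate 3. Lysosome genes had 5 risers and 2 that fell of 40 and did not pass (adjusted p = 0.897). Ctsb rose (0.92, SE 0.14, adjusted p = 0.00103) and Ctss fell (1886 ± 185 to 807 ± 282 CPM, adjusted p = 0.00118). Lysosome risers numbered 3 without day 1 replicate 3, day 3 replicate 1 or day 3 replicate 3, and 1 gene fell without day 1 replicate 1, day 3 replicate 2 or day 3 replicate 3.

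Of the marker lists that were lower at 1 day, the endothelial and the choroid plexus list passed as higher between 1 and 3 days. Endothelial markers rose in 9 of 15 cases (9 adjusted over the list alone, median 0.76, adjusted p = 9.51e-07, adjusted p = 0.0862 with an estimated correlation), with Slco1c1 from 36.3 ± 3.77 to 86.6 ± 10.3 CPM (adjusted p = 0.00149). Choroid plexus and ependyma markers rose in 4 of 8 cases (8 adjusted over the list alone, median 6.62, adjusted p = 3.74e-09, adjusted p = 0.157 with an estimated correlation). Of the 8, 1 rose without day 1 replicate 1 or day 1 replicate 3 and 2 without day 3 replicate 3. Folr1, Otx2, Kcnk1 and Lrriq1, 4 of the 8 largest rises, had no count at 1 day and were at least 120-fold, 218-fold, 184-fold and 122-fold higher at 3 days. The Otx2 call was lost in 4 of the 8 fits that leave out a library. Pld5 was at least 305-fold higher. Neutrophil markers fell in 2 of 13 cases, Csf3r and S100a8 (2 adjusted over the list alone, median −1.14, adjusted p = 0.00573, adjusted p = 0.157 with an estimated correlation), and in 5 without day 1 replicate 1. Mural (median 0.67, adjusted p = 0.057), monocyte (−1.13, 0.305), erythroid (2.12, 0.135), astrocyte (−0.38, 0.74) and border macrophage markers (−0.30, 0.0547) did not pass. Higher mural markers passed without day 1 replicate 1 (adjusted p = 0.0386), and lower border macrophage markers without control replicate 1 (0.0315), control replicate 2 (0.0292), day 1 replicate 1 (0.0448) or day 3 replicate 1 (0.0317).

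In all, 1912 of 17390 genes were called between 1 and 3 days, 912 higher and 1000 lower at 3 days. The share that was higher, 47.7%, was 54.2% without mitochondrially encoded genes and 92.0% with the choroid plexus covariate, both chosen after seeing the data, and 70.0% in a test against a 1.5-fold change. Of the called genes that changed over 2-fold, 730 were higher and 381 lower. Among the 8 largest falls, Mast1 (21.6 ± 7.53 to 2.54 ± 1.23 CPM, adjusted p = 0.00174) and Trim30c (17.2 ± 3.53 to 2.58 ± 0.995 CPM, adjusted p = 0.00161) fell with each library left out in turn. Mast1 shares 1616 exonic bases with Dnase2a on the other strand. Tas2r143, Hsf2bp, Fcrl5, Spata2l, Fhad1os2 and Tmem267 were at 9.51 CPM or less at 1 day and lost their call in 1 to 6 of the 8 such fits. The genes called, day 3 vs day 1, numbered 747 without day 3 replicate 3 and 1055 without day 3 replicate 1. With the choroid plexus marker level as a covariate, chosen after seeing the data, it called 25 (1154 at an unadjusted p under 0.05), with the median rise going from 1.80 (median SE 0.39) to 1.36 (0.81).

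**Figure D3:**
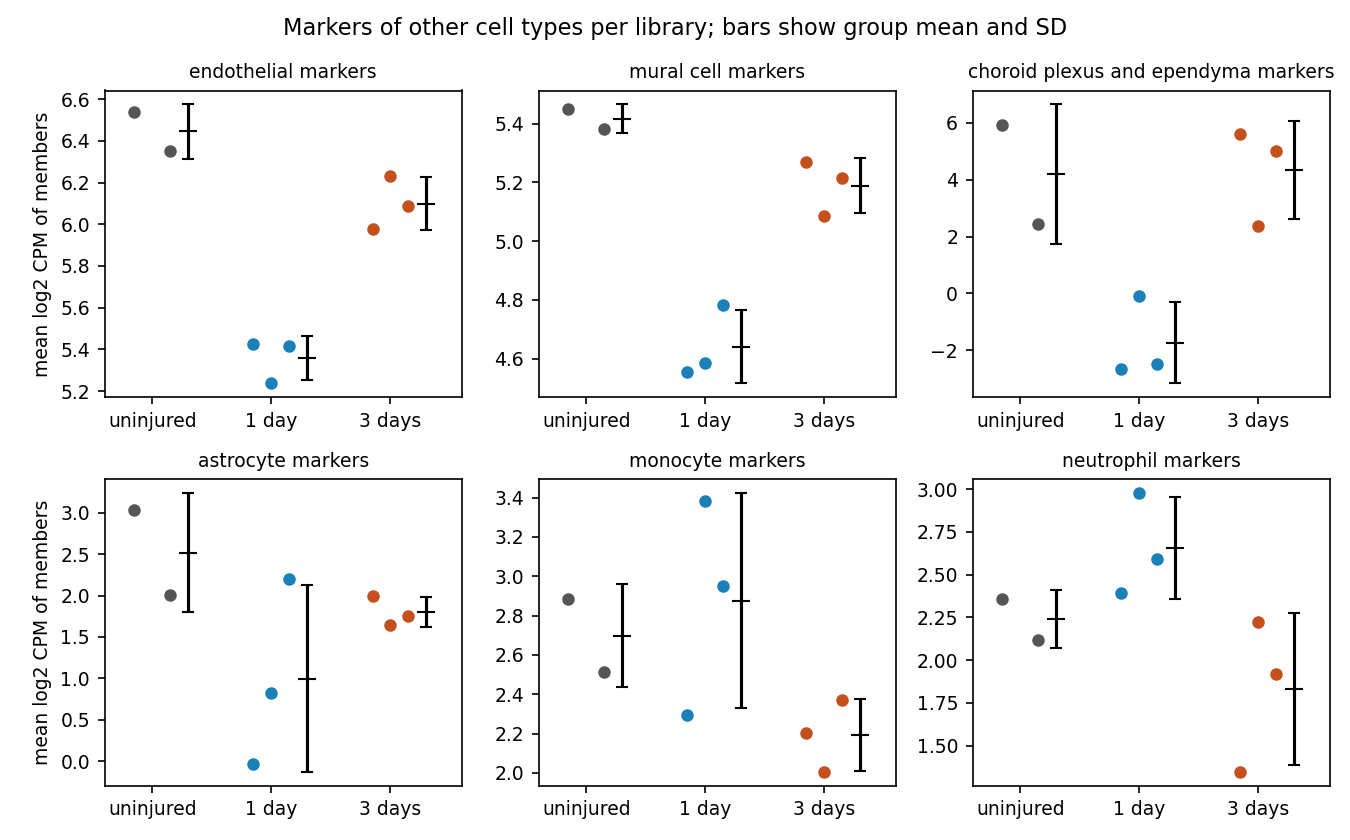
Mean log2 CPM of the tested members of 6 marker lists in each library (points) of uninjured mice (n = 2) and of mice 1 day (n = 3) and 3 days (n = 3) after crush, with bars for group mean and SD. Each panel has its own vertical scale, which does not start at 0. Endothelial markers averaged 6.44 in uninjured mice, 5.36 at 1 day and 6.10 at 3 days, and choroid plexus and ependyma markers ranged from 2.45 to 5.93 in uninjured libraries and from −2.64 to −0.09 at 1 day.

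Both injury comparisons used the same 2 uninjured libraries. Of the genes called, 28 had the same direction at 1 and 3 days: 21 rose, among them Il1b, Tnf, Il1rn, Gpr84, Tnfaip2, Ckap2l and the fibronectin receptor subunit gene Itga5, and 7 fell, among them Timp3 and Thbd. Tnf, Il1rn, Itga5, Timp3 and Thbd were chosen as examples after their values were seen. Independent lists of these sizes would share 2.64 risers and 1.99 that fell. The controls are too few to be split, so part of the excess may come from them. Across genes the log2 fold changes had a correlation of 0.30 and a covariance of 0.48. In 50 simulations of unchanged groups these were 0.61 and 0.56. There all libraries were simulated, and both comparisons shared 2 simulated uninjured libraries. Genes are not independent replicates. The overlap was 4 genes without control replicate 1, 14 without day 3 replicate 1, 9 without day 3 replicate 3 and 44 without day 1 replicate 3. A further 7 genes were called in opposite directions.

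7 lists passed in none of the 3 comparisons. The camera adjusted p ranged from 0.291 to 0.842 for type I interferon response genes, 0.5 to 0.962 for sterol synthesis genes, 0.0912 to 0.599 for lipid efflux and storage genes, 0.914 to 0.988 for neuron markers, 0.0568 to 0.841 for oligodendrocyte and precursor markers, 0.158 to 0.908 for monocyte markers and 0.343 to 0.809 for lymphocyte and NK cell markers. Some of them passed with 1 library left out: lipid genes at 3 days against uninjured mice without control replicate 1, day 1 replicate 2, day 1 replicate 3 or day 3 replicate 3 (0.0277 to 0.0392), and lower oligodendrocyte markers at 1 day without control replicate 1 (0.00565) or day 1 replicate 2 (0.0189). Neutrophil markers at 1 day (adjusted p = 0.0846) passed as higher without day 1 replicate 1 (0.0323), day 1 replicate 3 (0.0323) or day 3 replicate 1 (0.0447), and border macrophage markers at 1 day did not pass (0.957). With the choroid plexus covariate, chosen after seeing the data, lower monocyte markers passed between the times (adjusted p = 0.00653). Within the interferon list Cxcl10, the gene of an interferon-induced chemokine, rose at 3 days against uninjured mice from 64.7 ± 4.05 to 259 ± 47.4 CPM (2.00, SE 0.21, adjusted p = 0.000101). In the lists that passed, the median, mean and test had the same sign. They differed in sign in 13 tests of lists that did not pass: monocyte, border macrophage and lymphocyte markers at 1 day, complement genes and neuron markers at 3 days, and engulfment, lysosome, sterol synthesis and lipid genes and neuron, astrocyte, oligodendrocyte and lymphocyte markers between the times.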

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

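All tests below were chosen after seeing the results of the comparisons, and only for depth, genes that track choroid plexus level, transcript length and sample splits was the expected outcome written before the test's own result was seen.

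The groups at 1 and 3 days moved in opposite directions against uninjured mice, with the difference between them tested by edgeR or camera, in 10 results. Homeostatic microglia genes were higher as a list at 1 day and lower at 3 days, with a median log2 fold change of −0.67 between the times. With an estimated correlation between genes none of these 3 calls held (adjusted p = 0.304, 0.499 and 0.157), and the fall at 3 days was lost without control replicate 2 (adjusted p = 0.753). Immediate early and heat shock genes were higher at 1 day and lower at 3 days (−0.75 between the times). With an estimated correlation the difference between the times held (adjusted p = 0.0316) and the calls against uninjured mice did not (adjusted p = 0.126 and 0.14). Mitosis genes passed as lower at 1 day and as higher at 3 days (4.51 between the times). Their fall at 1 day was lost with an estimated correlation (adjusted p = 0.34) and without day 1 replicate 1 (adjusted p = 0.273), and over all genes 2 members rose and 1 fell, so the reversal is not established. Nusap1 (7.15) and Spag5 fell at 1 day and rose at 3 days. Spag5 had no count at 1 day, where its fitted value of 10.99 is no bound, and was at least 232-fold higher at 3 days. Itgam rose and then fell (−2.10). Of 4 genes outside the rule for named genes, chosen after their values were seen, Rai14 fell and then rose (2.43, with −1.15 at 1 day and 1.28 at 3 days against uninjured mice), while Slc24a1 (−2.02), Jmjd1c (−1.12) and Gm43430 (−1.50) rose and then fell. The fall of Itgam at 3 days against uninjured mice had an adjusted p of 0.0165 with all libraries and 0.336 without control replicate 1. It was also not called without day 3 replicate 1 or day 3 replicate 3. Groups of 2 and 3 were too small for the test of single samples far from their group.

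Vascular and choroid plexus markers were lower at 1 day. Fewer carried-over cells of every other type would lower all markers. Neuron markers with a mean of at least 5 CPM had a median log2 fold change of 0.44 (8 genes, quartiles −0.12 to 0.62). The upper quartile of 15 endothelial markers was −0.72. Over all 17 tested neuron markers the median was 0.50 and the mean 0.02. Their mean log2 CPM was 1.54 in uninjured mice and 1.26 at 1 day. Which cells these transcripts came from was not tested, so neuron markers argue only weakly against such a loss. Astrocyte (−0.17), mural (−0.25) and oligodendrocyte and precursor markers (−0.51) with a mean of at least 5 CPM had medians below 0. Fewer vascular and glial cells together therefore stay open. The restriction to 5 CPM was made after the result over all neuron markers was seen. Lower depth is argued against for endothelial markers alone by thinning every library to the smallest total. This left 10 of them called as falling, the number at full depth. Their mean log2 CPM was 6.44 in uninjured mice, a level at which thinning could change little. Choroid plexus markers, some with few counts such as Foxj1 (1.82 and 0 CPM in the uninjured pair), were not counted after thinning. Choroid plexus tissue carried into some dissections may account for part of the pattern. Those markers had a residual correlation of 0.93 between genes. All 8 were over 4-fold higher in control replicate 1 than in control replicate 2, a difference that also enters that correlation. Of the genes that fell at 1 day, 27.7% were at least 2-fold lower in day 3 replicate 2, which had low choroid plexus markers, than in the other day 3 libraries. In 10000 matched gene sets the median was 9.90% and the highest value 17.8%. The other 146 falling genes had a median of −1.78. For endothelial markers the choroid plexus covariate argues against this source. Their median fall was 1.13 (median SE 0.23) without it and 1.16 (0.47) with it, and all 15 stayed lower. That covariate separates the 1 day libraries from the rest. Whether the vascular fall came from dissection, from purification or from the injured tissue stays open.

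Mitosis and DNA replication genes were higher at 3 days. A rise of blood cells as large as that of mitosis genes is argued against by 31 monocyte, neutrophil and lymphocyte markers. These had a median log2 fold change of −0.47 and an upper quartile of 0.25, against a lower quartile of 3.42 for mitosis genes. In uninjured mice mitosis genes had a mean log2 CPM of 0.95, and monocyte, neutrophil and lymphocyte markers 2.70, 2.24 and 1.62. Folds from such unlike levels are not directly comparable. A smaller number of dividing blood cells therefore stays open. Of the 31, 0 were called as rising by edgeR or DESeq2, and 0 were higher at an unadjusted p under 0.05. A rise of vascular or glial cells of that size is argued against in the same way by 51 endothelial, mural, astrocyte and oligodendrocyte markers. These had a median of −0.45 and an upper quartile of −0.12. Their uninjured levels also differed from that of mitosis genes, with endothelial markers at 6.44. Division of vascular or glial cells already present was not tested. Of the 51, 0 were called as rising by edgeR or DESeq2, and 1 mural and 1 oligodendrocyte or precursor marker were higher at an unadjusted p under 0.05. Division of microglia after axon injury may account for the rise, a hypothesis found and tested on the same data, and dividing cells were not counted here.

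Nuclear-encoded oxidative phosphorylation genes have short exonic lengths (median 1908 bases against 3758 over all genes). By camera they were higher at 3 days with the preset correlation between genes (adjusted p = 4.14e-14) and did not pass with an estimated one (adjusted p = 0.108). A bias of counting toward genes of short exonic length is argued against as the whole cause. The list's median of 0.87 lay at percentile 100 among 10000 random lists matched on that length and expression. The medians of those lists centred on 0.23 and reached 0.76 at most. Those lists were drawn gene by gene, whereas the genes of this list vary together (estimated correlation 0.149). The percentile therefore does not allow for a shift shared by the list. Exonic length joins the exons of all annotated transcripts of a gene and can exceed that of the transcript present. A bias toward short transcripts therefore stays open. Reads shared with processed pseudogenes were not tested and may add to the levels of these genes.

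The 6 libraries of the 1 and 3 day groups make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 1912 genes and 1 split, the real one, gave as many; the highest of the others called 0 by edgeR, with 507 to 1316 genes at an unadjusted p under 0.05 against 4549 in the real split.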

How the results depend on the processing

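The choroid plexus covariate, leaving out mitochondrially encoded genes and thinning to equal depth were chosen after seeing the data, the other alternatives before. The genes called, day 1 vs control, numbered 308 with all libraries. They were 71 in a test against a 1.5-fold change, which asks for more, 909 with DESeq2, 110 with only the libraries of the 2 groups and 39 to 368 with 1 library left out. The cause of these differences was not tested. With the choroid plexus covariate, which separates the 1 day libraries from the others, edgeR called 0 (933 at an unadjusted p under 0.05). The replicate block gave 301, leaving out mitochondrially encoded genes 293 and thinning 307. The share that was higher, 34.4%, was 53.3% with limma-voom, 57.7% with sample weights and 16.5% with library size alone.

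The genes called, day 3 vs control, numbered 604. They were 167 against a 1.5-fold change, 1375 with DESeq2, 1498 with limma-voom and sample weights, 1345 with only the libraries of the 2 groups, 108 to 982 with 1 library left out, 495 with the covariate, 424 with the block, 605 without mitochondrially encoded genes and 618 thinned. A lone uninjured library is assumed to vary like the other groups.

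The genes called, day 3 vs day 1, numbered 1912. They were 463 against a 1.5-fold change, 3120 with DESeq2, 25 with the covariate, 747 to 2362 with 1 library left out, 1700 with the block, 1791 without mitochondrially encoded genes and 1877 thinned. Same-numbered libraries at 1 and 3 days had residual correlations of −0.03, −0.06 and −0.02. Those of uninjured mice had −0.02 and 0.02 with 1 day and 0.06 and 0.09 with 3 days. The last was the highest among all pairs from different groups. Whether replicate numbers pair the libraries stays open.

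Of the lists that passed, 15, 11 and 14, an estimated correlation left 1, 3 and 3. The size of the correlation does not explain all of these losses. Mural markers at 1 day had an estimate of 0.000517, under the preset 0.01, yet their unadjusted camera p rose from 0.000312 to 0.013. Glycolysis genes at 3 days against uninjured mice had an estimate of −0.0134, and their unadjusted camera p rose from 0.000145 to 0.00895. With fry, 8 lists passed at 1 day, 11 at 3 days and 16 between the times. At 1 day the covariate left 7. Between the times the covariate left 13: glycolysis genes and choroid plexus markers were lost and lower monocyte markers gained. The covariate is the mean level of those same choroid plexus markers. The loss of that list, there and at 1 day, was therefore fixed in advance. With the replicate block, lower homeostatic genes and border macrophage markers at 3 days against uninjured mice did not pass camera (adjusted p = 0.0682 for each). Lower astrocyte markers (0.014) and higher lipid genes (0.0203) passed there. With 1 library left out the lists numbered 13 to 16, 11 to 15 and 12 to 16. The overlap of genes called at day 1 and day 3 vs control, 28, was 119 with DESeq2, 82 at an adjusted p of 0.1 and 4 to 44 with 1 library left out. Choroid plexus and ependyma markers at 3 days against uninjured mice turned from lower to higher without control replicate 1, with an adjusted p of 0.00527, and the range over libraries left out was 0.00527 to 0.968. The uninjured library that then remains had the lower mean log2 CPM of these markers, 2.45 against 5.93, with a mean of 4.33 at 3 days.

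Over the alternatives chosen before seeing the data, values of single named genes were weaker in 497 cases, stronger in 194, reversed in 0 and otherwise the same in 6404. The covariate, leaving out mitochondrially encoded genes and thinning were not part of that tally. For lists, where they were included, the numbers were 75, 41, 1 and 1257. What was called in neither setting counts as the same, whatever its sign.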

Other observations

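The values below were singled out after they were seen, and no test was added for them.

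C1qa, the gene of 1 chain of complement component C1q, had group means of 34.0, 60.8 and 52.1 CPM in uninjured mice, at 1 day and at 3 days, while C1qb, the gene of another chain, had 1094, 1667 and 1529 CPM. Ckap2l, which lies directly downstream of Il1a on the same strand, had 19.0 and 19.9 CPM in uninjured libraries, 106, 112 and 71.0 CPM at 1 day and 121, 115 and 174 CPM at 3 days; Il1a had group means of 718, 2041 and 816 CPM.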
